A study of Mus musculus with 4 samples.

How the data were processed

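The series measured gene expression in mouse liver on 4 Affymetrix Mouse Gene 1.0 ST arrays, on which each probe set summarises short probes spread along a transcript. Per the labels and the series' design text, 2 genotypes were compared at 2 and at 8 months of age: wild type SIRT6 (WT) and mice with a conditional Sirt6 allele together with Cre recombinase under the albumin promoter, which is active in hepatocytes (labelled KO). RNA of 3 pairs of mice was combined for hybridization, so each group is 1 array of pooled RNA. Which mice made up a pair, their sex, their feeding state and the dates of collection or scanning were not given in the sources used here.

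The authors deposited log2 values that were made with RMA in Affymetrix Expression Console 1.0v, per the submitters' processing notes. RMA corrects the background, quantile normalizes the arrays it is run on and summarises probes into probe sets, which compresses differences of dim probe sets and hides any change in total RNA per cell. The log base is that of RMA and was not written in the table. Which arrays were normalized together, the probe annotation and the genome build were not given in the sources used here. The deposited values ran from 0.89 to 13.3, with medians of 3.57, 3.58, 3.52 and 3.56 for WT at 2 and 8 months and KO at 2 and 8 months, and none was missing. An array has no read depth. The number of arrays limits the precision here, and the spread between animals inside a pool cannot be measured.

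Of 35556 probe sets, 21789 had 1 gene symbol in the platform table, 1621 had several and 12146 were not listed there and are unnamed here. Only probe sets with 1 symbol were used for genes. Gene identifiers were looked up in the RefSeq table of assembly GRCm38.p6, which changed 0 symbols, and 91 probe sets whose identifier had no match kept the platform's symbol. This gave 19938 genes. For the 999 genes with more than 1 probe set, the probe sets were averaged on the log2 scale. Genes whose mean over the 4 arrays exceeded the 40th percentile of all genes, a value of 3.34, entered the comparisons, which left 11963 genes. No coordinates of the RefSeq table are printed, since the build of the array annotation is unknown.

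The comparisons, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says that a test was chosen afterwards. With 1 array per group, a difference between 2 arrays is a value with no test. Genes at least 1.5-fold apart were counted for KO minus WT at each age and for 8 minus 2 months in each genotype. The KO minus WT differences at the 2 ages share no array, so each is a repeat of the other in different pools at another age. The same holds for the age differences in the 2 genotypes. The test was an additive model of genotype and age fitted to all 4 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with an intensity trend and Benjamini-Hochberg adjustment over the 11963 genes at an adjusted p of 0.05. It has 1 residual degree of freedom per gene, the departure of genotype and age from additivity, which was moderated across genes with a prior of 11.3 degrees of freedom. Its p-values weigh the effect of genotype or age against that moderated departure. With 1 pool per group, they measure neither the spread between pools of a group nor that between animals. The words rose, fell and changed are used below only for genes past this threshold, and rose means a higher level in the KO-labelled arrays unless age is named.

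For 44 gene lists of liver pathways, stress responses and cell types, the median difference at each age was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list was said to lie beyond the random lists when its percentile was above 97.5 or below 2.5 on the same side at both ages. This describes these arrays and carries no p-value. Members that passed the additive model are given over all genes and, where the counts differ, adjusted over the list alone. Lists with fewer than 5 measured members got no percentile, which left 42.

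The named genes are Sirt6, every member of a list of key genes of SIRT6 and liver metabolism that passed the filter, the 10 highest and 10 lowest genes by mean difference among those at least 1.5-fold apart in the same direction at both ages, the 6 highest and 6 lowest for each difference between 2 arrays, the 2 highest and 2 lowest members of each list, and up to 20 genes by adjusted p. Symbols of predicted genes, small RNAs, nasal receptors and immunoglobulin or T cell receptor segments were counted but not named. Some key genes are not reported here.

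The fit was tested on 20 simulated sets of 11963 genes with 200 changed genes each. Repeated sets were used because the share of false calls in the first one proved variable. For the genotype effect it recovered 97 to 100% of 2-fold changes and 48 to 93% of 1.5-fold changes, with a median of 79.5%. Unchanged genes made up 2.34 to 28.4% of the called genes, with a median of 8.94%, so the share varied widely and was typically above the nominal level. It depends on the number of changed genes, which was set at 200 here and is unknown in the data. The noise was drawn from the fitted prior, and other residual degrees of freedom were not simulated. In the simulated set used for the counts, 0 unchanged genes were 1.5-fold apart in the same direction at both ages, and 10 of 10 lists shifted by 0.5 and 0 of 40 unshifted lists lay beyond the random lists. The simulated noise was independent between genes, unlike that of co-regulated genes, and the shift of 0.5 exceeds the medians of most lists below. The simulation therefore gauges neither false nor missed calls of the real lists.

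The alternatives were no expression filter or one at the 60th percentile, quantile normalization again, cyclic loess, centring on array medians, the brightest probe set of each gene, thresholds of 1.3-fold and 2-fold, eBayes without the trend or with robust estimation, no block for the other factor, an adjusted p of 0.1, unmatched random lists and the mean in place of the median. Values were read, summarised and drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.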

Results

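The study asked how the liver transcriptome of mice with the conditional Sirt6 allele and albumin-driven Cre differs from that of wild type mice, in young and in older adults. SIRT6 is a chromatin-bound, NAD-dependent deacetylase. Total RNA from liver was measured on 4 arrays, 1 for each of WT at 2 months, WT at 8 months, KO at 2 months and KO at 8 months, and each array held RNA pooled from 3 pairs of mice. There are no replicate arrays within a group, so differences at a single age carry no test.

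The targeted gene did not set the groups apart. The Sirt6 probe set read 4.55 and 4.50 in the WT arrays at 2 and 8 months and 4.54 and 4.46 in the KO arrays, all on the log2 scale. KO minus WT was -0.01 at 2 months and -0.05 at 8 months, with a limma adjusted p of 0.92. Which exons the probe set covers and which exons the conditional allele loses were not given in the sources used here, so the value neither bears out nor excludes the labels. The groups are therefore called KO-labelled and WT-labelled arrays, and every direction of a genotype difference below rests on those labels.

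Immediate early genes, transcription factors and regulators that cells switch on within minutes of a stimulus, led the genes that were higher in the KO-labelled arrays at both ages. Fos was higher by 3.62 log2 units at 2 months and 3.78 at 8 months, Btg2 by 3.41 and 3.54, Egr2 by 3.13 and 2.83, Jun by 2.72 and 2.93, and the stress-induced transcription factor Atf3 by 2.71 and 2.76. The other genes among the 10 highest were Btbd19 with a mean of 3.44, the lipocalin Obp2a with 2.53 and 3.58, the actin-severing protein gelsolin (Gsn) with 2.81 and 3.17, the NKG2D ligand Raet1d with 3.53 and 2.39, and the thyroxine-binding globulin Serpina7 with 2.70 and 2.38. The lowest was Gstp3, a glutathione transferase of the pi class, at -4.36 and -4.26. It was followed by the metallothionein Mt2 at -3.09 and -3.71, the arrestin-domain gene Arrdc3 at -2.74 and -3.08, the G protein regulator Rgs16 at -2.90 and -2.63, the glucocorticoid-induced immunophilin Fkbp5 at -2.17 and -3.26 and the zinc finger factor Zbtb16 with a mean of -1.99. The remaining genes of the 10 lowest were the smooth muscle actin Acta2, the fatty acid omega-hydroxylase Cyp4a10, Cyp3a13 and Clec2h, with mean differences of -1.94, -1.72, -1.68 and -1.65. Sequence variants under the probes also alter array values, and whether they contribute to extreme differences such as those of Gstp3, Mt2 and Raet1d was not tested.

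In total 340 of 11963 genes were at least 1.5-fold apart in the same direction at both ages, 213 of them higher and 127 lower in the KO-labelled arrays. Only 1 gene, Adcy4, was 1.5-fold apart in opposite directions. Of these genes, 78 were at least 2-fold higher and 32 at least 2-fold lower at both ages. Across genes, which are not independent replicates, the genotype difference at 2 months correlated with that at 8 months with a Pearson r of 0.68 and a Spearman rho of 0.50, and 66.2% of genes had the same sign at both ages. The additive limma model called 1325 genes for genotype, 815 that rose and 510 that fell, with 2987 genes at an unadjusted p under 0.05. All 340 genes were among the 1325. The smallest adjusted p-values were 8.4e-12 for Gstp3 with a mean difference of -4.31 (SE 0.08), 1.9e-10 for Btg2 with 3.48 (SE 0.09) and 2.4e-10 for Fos with 3.70 (SE 0.10), each from 2 arrays per genotype. Nr4a1, Dnajb1, Egr1, Hamp2, Cyp2b9, Ppp1r10 and Ier2 were also among the 20 smallest and rose by 1.71 to 2.40. The count was 752 without the expression filter and 846 without the intensity trend, and it depends on 1 residual degree of freedom.

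**Figure D1:**
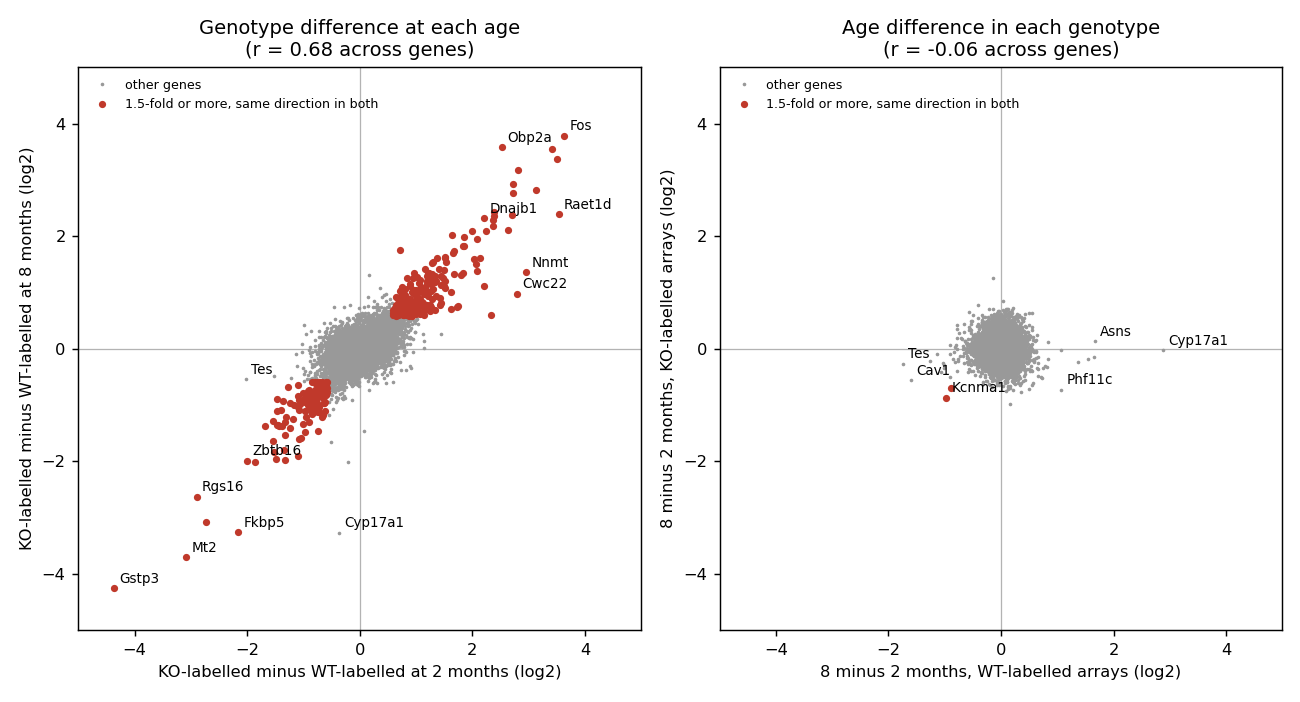
Left, each of 11963 genes by its KO-labelled minus WT-labelled difference at 2 months (x axis, log2) and at 8 months (y axis, log2), with the 340 genes at least 1.5-fold apart in the same direction at both ages in red. Right, the same genes by the 8 minus 2 months difference in the WT-labelled (x axis, log2) and KO-labelled arrays (y axis, log2), where 2 genes met that criterion, so the genotype differences line up along the diagonal (r = 0.68) and the age differences do not (r = -0.06).

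At 2 months the KO-labelled array had 476 genes at least 1.5-fold higher and 286 lower than the WT-labelled array. Besides genes named above, the most extreme were nicotinamide N-methyltransferase (Nnmt), higher by 2.96, and the focal adhesion gene Tes, at -2.02. At 8 months 288 genes were higher and 231 lower. Here the steroid hydroxylase Cyp17a1 stood apart, at -3.27 against -0.37 at 2 months, because its level was 6.16 in the WT-labelled array at 8 months and between 2.89 and 3.29 in the other arrays. Nnmt was higher by 1.36 and Tes was at -0.54 at 8 months. At 2 and 8 months Nnmt read 4.43 and 5.80 and Tes 5.76 and 4.02 in the WT-labelled arrays. In the KO-labelled arrays they read 7.38 and 7.15, and 3.74 and 3.47. Whether these genotype differences changed between the ages could not be tested with 1 array per group.

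The list of immediate early genes had 25 measured members, of which 17 rose, 1 fell and 7 did not pass the test. Its median difference was 1.00 at 2 months and 1.12 at 8 months, above all 10000 random lists at both ages, and 16 members were at least 1.5-fold higher at both. The member that fell was Klf10, with a mean of -0.88 and an adjusted p of 0.00018, and Klf4 was at -0.34 and -0.14 without passing. Of 18 heat shock genes, 11 rose and 0 fell, with a list median of 0.45 and 0.38 (12 adjusted over the list alone). The chaperones Dnajb1 and Hspa1a led with 2.21 and 2.31, and 1.02 and 0.94, while the mitochondrial chaperone Hspd1 was at 0.08 and -0.09 and Ahsa1 at 0.11 and -0.02. Of 28 genes of endoplasmic reticulum stress and the integrated stress response, 13 rose and 1 fell (15 and 4 adjusted over the list alone), with medians of 0.28 and 0.14. Atf3, which is also an immediate early gene, and the pro-apoptotic factor Ddit3, with 1.45 and 0.82, were the highest. The pseudokinase Trib3 fell by 0.87 on average, and the asparagine synthetase Asns was at 0.07 and -1.46. All 3 lists lay beyond the random lists at both ages.

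**Figure D2:**
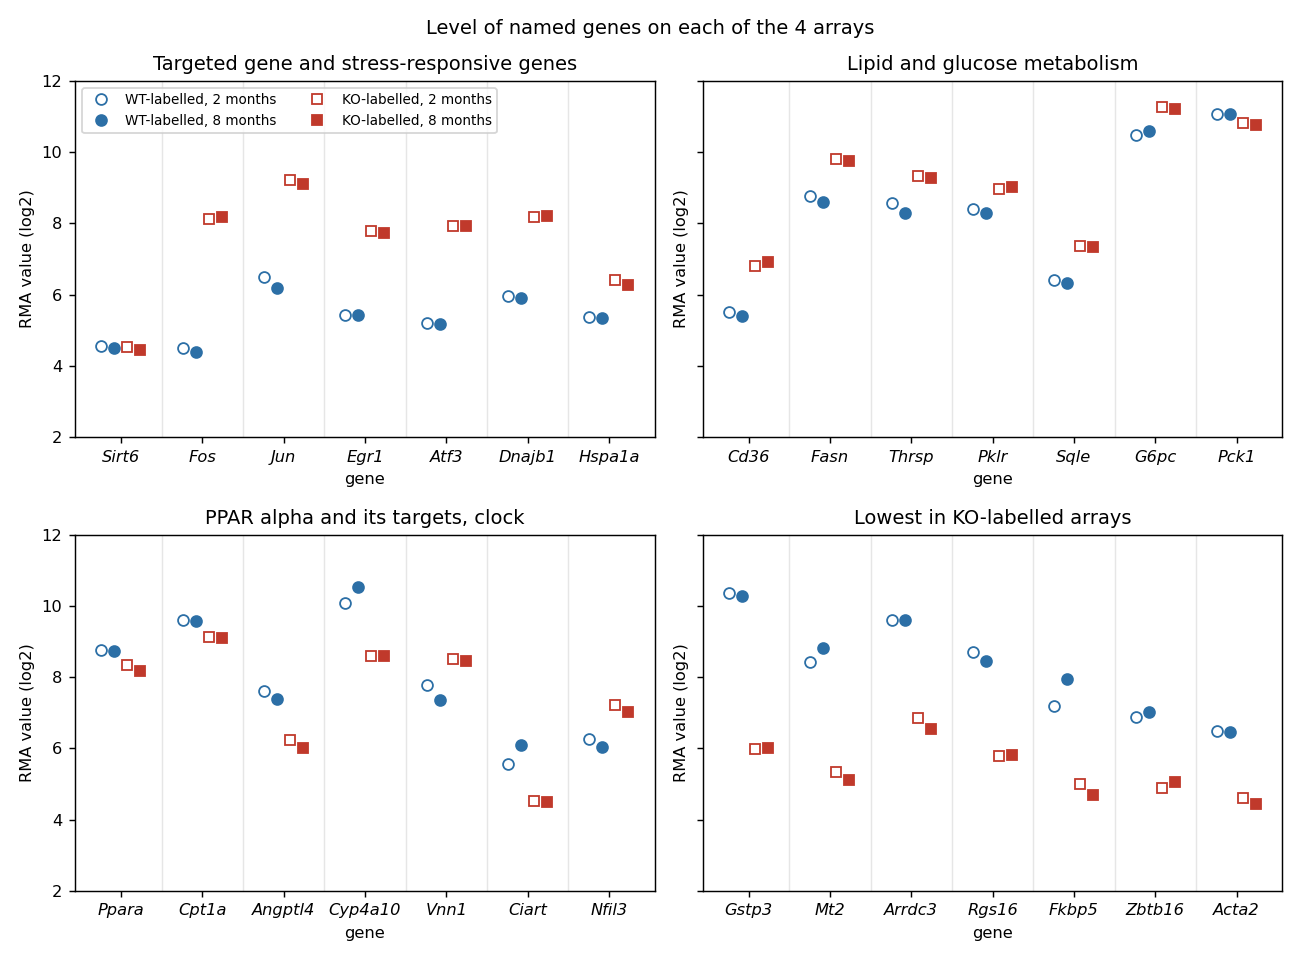
RMA values (y axis, log2) of named genes (x axis) on each of the 4 arrays, with circles for WT-labelled and squares for KO-labelled arrays, open at 2 months and filled at 8 months, and 1 array per symbol. Sirt6 lay between 4.46 and 4.55 on all 4 arrays, whereas Fos was at 4.49 and 4.39 in the WT-labelled and at 8.12 and 8.17 in the KO-labelled arrays.

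Genes of fatty acid and cholesterol synthesis were higher and targets of PPAR alpha, the nuclear receptor that drives hepatic fatty acid oxidation, were lower in the KO-labelled arrays. Of 20 fatty acid synthesis genes, 9 rose and 2 fell (10 and 2 adjusted over the list alone), with medians of 0.29 and 0.25 beyond the random lists, though the mean of members was narrowly inside them at 2 months. Fatty acid synthase (Fasn) was higher by 1.05 at 2 months and 1.17 at 8 months (adjusted p 1.2e-06) and the lipogenic protein Thrsp by 0.75 and 0.97. Acaca, Elovl6 and Acly rose by means of 0.70, 0.68 and 0.49, and Srebf1, which encodes the transcription factor of lipogenesis, and Scd1 by 0.45 and 0.28. The carboxylase isoform Acacb fell, with -0.58 and -0.79, and so did the desaturase Fads2, with -0.35 and -0.48. The glucose-responsive factor Mlxipl was at -0.21 and -0.17 with an adjusted p of 0.19. Of 20 cholesterol synthesis genes, 9 rose and 1 fell (11 and 1 adjusted over the list alone), with medians of 0.27 and 0.24 beyond the random lists. Squalene epoxidase (Sqle), with 0.95 and 1.01, and Pmvk, with 0.71 and 1.03, were the highest, Tm7sf2 fell, with -0.37 and -0.41, and Hsd17b7 was at -0.07 and -0.14.

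Of 17 PPAR alpha targets, 12 fell, 1 rose and 4 did not pass, with medians of -0.49 and -0.45 that lay below all random lists at both ages. The omega-hydroxylases Cyp4a10 and Cyp4a31, neighbouring genes of close sequence that probes may not fully separate, were at -1.49 and -1.96, and -1.10 and -1.91. The lipase inhibitor Angptl4 was at -1.37 and -1.38. The pantetheinase Vnn1 rose, with 0.74 and 1.10, and the pyruvate dehydrogenase kinase Pdk4 was at 0.00 and 0.14. Ppara itself fell, with -0.42 and -0.57 and an adjusted p of 0.0015, as did the rate-limiting carnitine transferase Cpt1a, with -0.49 and -0.47, and the hepatokine Fgf21, with -0.53 and -0.40. In the list of 24 fatty acid oxidation genes, 6 fell and 0 rose, Acadm was at -0.09 and -0.03, Crot at 0.24 and 0.17 and Hadh at 0.19 and 0.21. Its medians, -0.05 and -0.10, lay beyond the matched random lists only at 2 months and beyond unmatched ones only at 8 months. The mean of members was inside the random lists at both ages.

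Of 26 genes of triglyceride synthesis and fatty acid uptake, 3 rose and 4 fell (4 and 6 adjusted over the list alone), with medians of -0.05 at both ages. The fatty acid transporter Cd36 rose most, with 1.29 and 1.53, followed by the acyltransferase Mogat1, while Fabp5 and Fabp2 fell by 0.64 and 0.63. Among 17 genes of lipid droplets and lipolysis, 2 rose and 6 fell, with medians of -0.24 and -0.04. The lipase inhibitor G0s2 fell by 1.29 and the droplet protein Plin5 by 0.75, and Fitm1 and Hsd17b13 rose by 0.74 and 0.65. Of 19 lipoprotein genes 1 rose, the cholesterol exporter Abca1 with 0.31, and 5 fell, among them Angptl4 and Apoa4, the latter by 0.99. Pltp was at 0.18 and 0.24, the list medians were -0.03 and -0.13, and adjusted over the list alone 6 fell. Pparg, the receptor that drives lipid storage, was higher by 0.53 and 0.61 (adjusted p 0.0028).

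In glucose metabolism the glycolysis list did not move as a unit in either direction. Of 19 glycolysis genes, 3 rose and 4 fell (4 and 5 adjusted over the list alone), with medians of -0.05 and -0.02 inside the random lists and a mean that was 0.00 at 8 months. Liver pyruvate kinase (Pklr) rose, with 0.58 and 0.73 (adjusted p 0.00017), and so did Pfkfb3, with 0.46 and 0.52, whereas Aldoc and Eno3 fell by 0.68 and 0.50. The glucose transporter Slc2a1 fell, with -0.46 and -0.32, a call lost when arrays were centred on their medians (adjusted p 0.056). Pfkl was at -0.17 and 0.14 and Ldha at -0.12 and -0.02. Of 14 gluconeogenesis genes, 7 fell and 1 rose (7 and 3 adjusted over the list alone), with medians of -0.18 and -0.23 beyond the random lists, though the means of members, -0.08 and -0.16, were inside them at both ages. The member that rose was the catalytic subunit of glucose-6-phosphatase (G6pc), with 0.79 and 0.62, while the transporter subunit Slc37a4 fell, with -0.63 and -0.65, as did Got1, with -0.45 and -0.74. Pck1 fell, with -0.25 and -0.30 and an adjusted p of 0.030, a call also lost under median centring (adjusted p 0.105). The coactivator Ppargc1a was at 0.65 and 0.21 and passed only under cyclic loess.

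Of the 26 measured key genes, which overlap the metabolic lists, 11 rose, 6 fell and 9 did not pass (12 and 6 adjusted over the list alone), with medians of 0.32 and 0.14 beyond the random lists, though the mean of members was inside them at 2 months. Besides genes given above, the thioredoxin-interacting protein Txnip fell by 1.40 and the insulin-repressed Igfbp1 rose by 0.65. The bile acid enzyme Cyp7a1 was at 0.47 and -0.31 and Igf1 at 0.31 and -0.01, and neither passed. In the list of the insulin and IGF axis, 5 of 26 rose and 5 fell, with medians of 0.06 and 0.05, Trib1 and Irs2 rising by 1.06 and 0.90 and Igfbp2 falling with Trib3, at a mean of -1.43.

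Conjugating enzymes were higher in the KO-labelled arrays. Of 25 phase II and antioxidant genes, 12 rose and 1 fell (15 and 2 adjusted over the list alone), with medians of 0.35 and 0.20 beyond the random lists. Gstm3 led with 1.48 and 1.25, Sult5a1 followed with 0.74 and 0.71, Gstt2 fell with -0.78 and -0.91, and Sult1d1 was at -0.11 and -0.50. Gstp3, the lowest gene of all, was not in this list. Of 21 xenobiotic cytochrome P450 genes, 2 rose and 2 fell (3 and 3 adjusted over the list alone), with medians of 0.09 and -0.12. The female-biased, closely related Cyp2b13 and Cyp2b9 rose by 1.92 and 1.71, and Cyp3a13 and Cyp2d22 fell, the latter by 0.36. Among 9 female-biased genes 2 rose and 4 fell, with medians of -0.18 and -0.13, the lowest being Cyp17a1 and the monooxygenase Fmo2, with a mean of -1.41. Among 19 male-biased genes 5 rose and 3 fell (8 and 4 adjusted over the list alone, medians 0.24 and 0.01, where Xist was also at -1.76 and -0.79), with Cyp4a12b and Selenbp2 at 0.61 and 0.60 and the complement genes C6 and C8b at -0.60 and -0.39. Of 21 bile acid genes, 3 rose, led by Abcc4 and Akr1d1 with 0.75 and 0.58, and 7 fell, led by Cyp8b1 and Baat with -0.93 and -0.66 (3 and 8 adjusted over the list alone, medians 0.06 and -0.07). The clock list had 3 of 20 genes that rose, led by Nfil3 and Bhlhe40 with 0.97 and 0.48, and 7 that fell, led by Ciart and Usp2 with -1.32 and -0.97 (4 and 8 adjusted over the list alone, medians -0.06 and -0.08). The medians of these sex-biased, bile acid and clock lists did not lie beyond the random lists at both ages.

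Markers of other cell types moved in different directions. Of 20 Kupffer cell and macrophage genes, 4 rose and 1 fell (7 and 1 adjusted over the list alone), with medians of 0.14 and 0.37, the latter above all random lists and the former just inside the threshold. Cd5l and Vsig4 rose by 0.72 and 0.49, the lysozyme Lyz2 fell by 0.52 and Lyz1 was at -0.47 and -0.24. Of 25 stellate cell and fibrosis genes, 3 rose and 7 fell. The medians of -0.08 and -0.14 lay inside the random lists at 2 months (percentile 5.06) and below them at 8 months (percentile 0.18). The mean of members, -0.25 and -0.10, lay below all random lists at 2 months but inside them at 8 months. Acta2 had a mean of -1.94, and Vim was at -1.23 and -0.52, with levels of 7.72 and 6.71 in the WT-labelled and 6.50 and 6.20 in the KO-labelled arrays, and Ccn2 and Col4a2 rose by 0.61 and 0.45. Of 5 erythroid genes 2 rose (3 and 1 that fell adjusted over the list alone), Car1 and Alas2 by 0.73 and 0.64, Klf1 was at -0.43 and -0.38 and Slc4a1 at 0.15 and 0.28, and the medians of 0.33 and 0.28 lay beyond the random lists, but not under quantile normalization again, under cyclic loess or, at 2 months, by the mean of members. Endothelial markers had 1 of 20 genes that rose, Cdh5 by 0.45, with Lyve1 at 0.63 and 0.26, Vwf at -0.20 and -0.21, Stab1 at -0.12 and -0.25 and medians of -0.04 and -0.06. Of 8 cholangiocyte genes Anxa5 rose by 0.71 and Krt23 fell by 0.66, with Krt18 at 0.36 and 0.15 and Sox4 at -0.46 and -0.12 (2 rose and 1 fell adjusted over the list alone, medians -0.07 and 0.02). None of 4 lymphocyte and neutrophil genes, 10 genes of adipose, pancreas and muscle tissue and 19 secreted proteins of hepatocytes passed the test, and their medians lay between -0.08 and 0.04. Hepatocyte transcription factors had 2 of 19 that rose, Onecut1 and Prox1 by 0.94 and 0.41, and 3 that fell, among them the xenobiotic receptor Nr1i3 (CAR) by 0.95 and Ppara (3 and 5 adjusted over the list alone, medians 0.03 and -0.02). Pericentral genes had 2 of 19 that rose, Gstm3 and Lgr5, and 2 that fell, Cyp27a1 and Slc1a2, the latter not under median centring (3 and 2 adjusted over the list alone, medians 0.07 and -0.12). Periportal zonation had 2 of 14 that rose, Hsd17b13 and Aldh1b1, and 4 that fell, the lowest being Slc25a47 at -0.97 and Igfals at -0.49 (2 and 6 adjusted over the list alone, medians 0.03 and -0.10).

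Inflammatory lists differed among themselves. Of 18 interferon-stimulated genes, 4 rose and 0 fell, with medians of 0.24 and 0.19 beyond the random lists, led by Ifi27 with 1.27 at both ages and Iigp1 with 0.83 and 0.54, while Psmb8 was at -0.43 and -0.15 and Tap1 at -0.31 and -0.19. Of 25 acute phase genes, 7 rose and 4 fell (9 and 4 adjusted over the list alone), with the hepcidin Hamp2 and the pentraxin Apcs at means of 2.36 and 1.29 and Mt2 and Serpina3n at -3.40 and -0.49, and medians of 0.24 and -0.01. Of 18 NF-kB targets, 3 rose and 1 fell, with Il1b at 1.00, Cxcl9 at 0.67, Nfkbia at -0.44 and Tnfaip3 at -0.06 and -0.38 (4 and 1 adjusted over the list alone, medians 0.02 and 0.05). Of 6 genes of antigen presentation, Cd74 rose by 0.72 and H2-Eb1 fell by 0.96, with Ctss at 0.10 and 0.52 and H2-DMa at -0.20 and -0.14 (2 and 1 adjusted over the list alone, medians 0.06 and 0.08).

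Of 28 ribosomal protein genes, 0 rose and 2 fell, Rps19 and Rps18 by 0.34 and 0.27, and both calls were lost under median centring (adjusted p 0.069 and 0.107), and 0 fell adjusted over the list alone. The medians of -0.06 and -0.16 lay beyond the matched random lists, but at 2 months neither beyond unmatched ones nor by the mean of members, with Rpl5 at 0.30 and -0.12 and Rpl26 at -0.11 and 0.17. Of 22 p53 targets, 6 rose and 2 fell, led by Btg2 and Plk3, with a mean of 1.55, against Gadd45b and Sesn1, with -1.24 and -0.57 (8 and 2 adjusted over the list alone, medians 0.07 and 0.09). Of 17 cell cycle genes, the cyclin Ccnd1 rose by 0.46 and Tk1 and E2f8 fell by 0.91 and 0.90, with Ccne1 at 0.33 and 0.47 (2 and 3 adjusted over the list alone, medians -0.27 and 0.00). Of 26 DNA repair genes, Xrcc4 and Lig4, partners in end joining, rose by 0.68 and 0.45, and Xpa and Ercc1 were at means of -0.34 and -0.27 without passing, around list medians of 0.04 and -0.04. Of 22 sirtuin and NAD genes, 3 rose, Nnmt and Aox1 by 2.16 and 0.36 among them, and 1 fell, Sirt7 by 0.39, with Nmrk1 at -0.33 and -0.32 (3 and 4 adjusted over the list alone, medians 0.01 and -0.05). In oxidative phosphorylation 2 of 38 rose, Ndufb3 and Ndufa1 by 0.66 and 0.33, the latter not under quantile normalization again (adjusted p 0.062), and adjusted over the list alone 1 rose. Its medians were -0.00 and -0.03. Among 21 HIF1 targets 2 rose and 4 fell, with Egln3 at 0.52, Adm at 0.63 and 0.20, and Aldoc and Ndrg1 at -0.68 and -0.41 (3 and 5 adjusted over the list alone, medians -0.12 and -0.06). Among 25 genes of the urea cycle and amino acid catabolism, 2 rose, Gldc and Kmo by 0.39 and 0.36, and 5 fell, led by Asl and Prodh with -0.77 and -0.69 (4 and 7 adjusted over the list alone, medians -0.02 and -0.13). Of 3 sex chromosome genes none passed over all genes and 1 rose adjusted over the list alone. Altogether 9 of 42 lists lay above and 3 below the random lists at both ages. For 12 lists the median and the mean had different signs at 1 age or both, namely glycolysis, female-biased, acute phase, endothelial, adipose and pancreas and muscle, hepatocyte transcription factor, pericentral, periportal, cell cycle, oxidative phosphorylation, sirtuin and DNA repair genes, so no direction is given for them as lists.

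**Figure D3:**
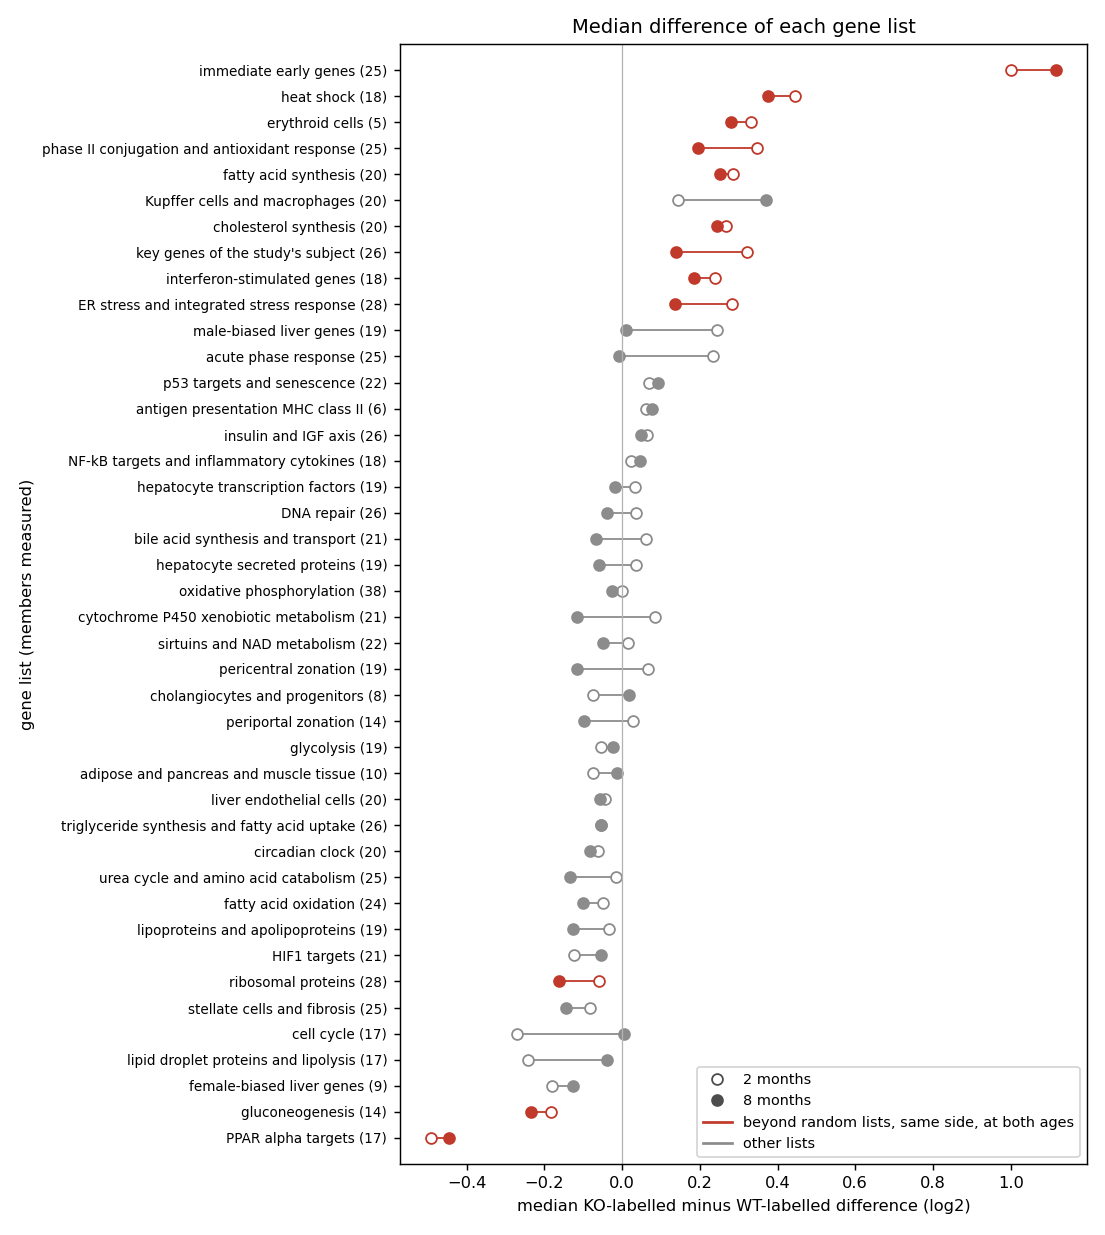
Median KO-labelled minus WT-labelled difference (x axis, log2) of each of 42 gene lists (y axis, with the number of measured members), open circles at 2 months and filled circles at 8 months, with the 12 lists beyond the random lists on the same side at both ages in red. Immediate early genes stand highest at 1.00 and 1.12, and PPAR alpha targets lowest at -0.49 and -0.45.

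The age comparison asked what differs between 2 and 8 months within each genotype. In the WT-labelled arrays the largest differences were higher levels at 8 months of Cyp17a1, by 2.87, Asns, by 1.66, the splicing factor Cwc22, by 1.65, Fam171b, by 1.55, Nnmt, by 1.37, and Phf11c, by 1.07. Tes was at -1.75, the caveolin Cav1 at -1.60, the serine protease Htra1 at -1.26, Obp2a at -1.15, Anxa1 at -1.07 and the galectin Lgals1 at -1.04. In the KO-labelled arrays the same genes differed by between -0.73 and 0.14. There the highest named genes were Smim41, Pate11, Ifna5, Lhb, Cela3b and Cabp4, with 0.70 to 0.77, and the lowest were Kcnma1 at -0.87, Zfp457 at -0.77, Phf11c at -0.73, Gkap1 at -0.73, Smim26 at -0.72 and Bcap29 at -0.72. The levels of these 12 genes in the KO-labelled arrays lay between 2.91 and 6.34. At least 1.5-fold apart were 25 genes higher and 53 lower at 8 months in the WT-labelled arrays, and 45 higher and 33 lower in the KO-labelled arrays. The latter split depends on the scaling, with 27 higher and 43 lower under cyclic loess and 23 and 56 under median centring.

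Only 2 genes were 1.5-fold apart by age in the same direction in both genotypes, both lower at 8 months. These were the lysozyme Lyz2, made by macrophages and other myeloid cells, with -0.90 in the WT-labelled and -0.70 in the KO-labelled arrays, and the potassium channel Kcnma1, with -0.98 and -0.87. The probe sets of Kcnma1 disagree for genotype, with -0.08 and -0.14 for one at a mean level of 2.51 and -2.85 and -2.56 for the other at 5.59. Phf11c was 1.5-fold apart in opposite directions. Across genes the age differences in the 2 genotypes correlated with r = -0.06 and rho = -0.09, and 46.5% of genes had the same sign. The additive limma model called 1 gene for age, Lyz2, which fell by 0.80 (SE 0.10, adjusted p 0.0395), with 431 genes at an unadjusted p under 0.05. The count was 0 without the filter, under quantile normalization again, without the trend and with robust estimation, and 17 under cyclic loess.

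Of the 42 lists, 12 lay beyond the random lists by age in the WT-labelled and 5 in the KO-labelled arrays, and 0 in both on the same side. These counts use the median. By the mean of members, Kupffer cell genes lay below the random lists by age in both genotypes, at -0.27 in the WT-labelled and -0.13 in the KO-labelled arrays. In the WT-labelled arrays Kupffer cell genes were lower at 8 months with a median of -0.27, cholangiocyte genes with -0.27, cell cycle genes with -0.14 and fatty acid synthesis genes with -0.10. Bile acid, xenobiotic P450, male-biased and urea cycle genes were higher, with medians of 0.12, 0.12, 0.12 and 0.08. The other lists below the random lists there were glycolysis, immediate early, key and lipid droplet genes, with -0.07, -0.07, -0.06 and -0.05, but none of these 4 lay beyond unmatched random lists. Stellate cell genes had a median of -0.07 just inside the random lists and a mean of -0.20 below all of them. The WT-labelled array at 2 months read highest for Cav1, 6.18 against 4.10 to 4.66, and Vim, 7.72 against 6.20 to 6.71. It read lowest for Cd5l, 5.61 against 5.72 to 6.45. With 1 pool per age, the differences of the cell type lists cannot be told apart from a difference between pools. The sex of the pooled mice is not given, and in the WT-labelled arrays Xist read 4.42 at 2 and 3.08 at 8 months, so the difference of male-biased genes is not assigned to age alone. In the KO-labelled arrays the medians of ribosomal protein, phase II, xenobiotic P450 and acute phase genes were -0.14, -0.13, -0.12 and -0.10, below the random lists, and that of cholesterol synthesis genes was -0.01, above the matched but not the unmatched ones. Xenobiotic P450 genes thus lay above the random lists by age in one genotype and below them in the other, and this difference was not tested.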

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

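The tests below were chosen after the result they weigh was seen, except that on linked genomic segments.

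The genotype difference of Adcy4, an adenylate cyclase, was 0.59 at 2 months and -0.60 at 8 months, opposite signs that differ by -1.19. The age difference of Phf11c was 1.07 in the WT-labelled and -0.73 in the KO-labelled arrays, which differ by -1.80. Neither difference was tested, since each rests on 4 arrays with 1 per group. Among probe sets left out of the gene comparisons, 148 of 5192 above the expression filter and without a gene symbol were at least 1.5-fold higher in the KO-labelled arrays at both ages, 110 were lower and 99 were apart in opposite directions. Among 849 probe sets with several symbols, 42 were higher, 9 lower and 0 in opposite directions.

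The first pattern weighed is the set of 340 genes at least 1.5-fold apart between the genotype labels in the same direction at both ages. The split that would be the true one after an exchange of a KO and a WT array at one age separated 0 genes by 1.5-fold, against 294 for the labelled split, but this follows from the pattern itself, and with Sirt6 level on all arrays an exchange cannot be told apart from correct labels. Genetic background that differs between the mice of the 2 genotypes could also hold levels apart at both ages. Of 338 pattern genes with a position, 15.4% had another pattern gene of a different name stem among the 2 measured genes on either side, against a median of 10.4% and a highest value of 19.5% in 10000 random sets, among which it stood at percentile 98.0. A percentile above 99 had been set in advance as a fit, so linked segments cannot be told apart from the genotype here, and 3 of the 40 measured neighbours of Sirt6 belonged to the pattern against 2.83% of all genes.

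The second pattern is the higher level of immediate early and heat shock genes in the KO-labelled arrays. The median absolute difference between ages within a genotype was 0.13 of that between genotypes (0.09 against 0.71 over 43 genes). Handling stress that struck pools at random still cannot be told apart from the genotype, because 2 stressed pools among 4 would fall on the same label in 1 of 3 ways to part them evenly. Collection or hybridization that followed the genotype would give the same picture, and 0 arrays have a date in the labels, so it cannot be told apart from the genotype. A biological difference in stress signalling between the genotypes stays open and was not tested.

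The third pattern is the lower level of PPAR alpha targets together with the higher level of fatty acid synthesis genes. Fed KO-labelled and fasted WT-labelled pools cannot be told apart from the genotype. A list of 7 fasting-induced genes had a median difference of 0.43 (0.65 at 2 and 0.21 at 8 months), with 3 that rose and 1 that fell. It overlaps the other lists, since Pdk4 is also a PPAR alpha target and G6pc and Ppargc1a are also gluconeogenesis genes. The gluconeogenesis list went the other way with medians of -0.18 and -0.23. A different time of day at collection may contribute but cannot be told apart from the genotype. The median of Arntl-phase genes minus that of Dbp-phase genes was 0.71 (0.81 and 0.61), above 99.98 and 99.96% of random gene sets. Of these genes, 1 of 4 Arntl-phase genes rose and 6 of 9 Dbp-phase genes fell. The phase lists were chosen after the data were seen and hold Nfil3, Ciart and Usp2, extremes of the clock list. Per1 and Bhlhe40, which rose, are in neither, so these percentiles decide nothing. The clock list fixed beforehand lay inside the random lists, at percentiles 2.73 and 4.39. It mixes genes of both phases, with 3 of 20 that rose and 7 that fell, and opposite differences can cancel in its median. Its place inside the random lists therefore does not argue against a different time of day. Lower glucocorticoid exposure cannot be told apart from the genotype, since 4 of 17 glucocorticoid-induced genes rose and 7 fell around a median of -0.11, at percentiles 4.52 and 2.3 of random gene sets, and a biological effect of SIRT6 on these genes stays open and untested.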

How the results depend on the processing

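Counts of genes at least 1.5-fold apart between the genotypes stayed within 1.5 times of the reported ones under every filter, scaling and probe set choice, and the shared count ranged from 280 to 354. Pairing the arrays across the ages, chosen after the data were seen, gave 340. With a 2-fold threshold the counts were 166 at 2 months, 150 at 8 months, 110 at both, 15 by age in WT, 1 by age in KO and 0 in both genotypes, and with 1.3-fold 2263, 1392, 793, 390, 634 and 21, as a stricter or looser threshold implies. The 60th percentile filter left 41 genes by age in WT, 25 in KO and 1 in both, and no filter gave 120 in KO. The genotype model called 752 genes without the filter, 729 of them among the reported 1325, and 846 without the trend. The age model called 0 genes without the filter, under quantile normalization again, without the trend, with robust estimation and without the genotype block, 2 under median centring, with the brightest probe set and at an adjusted p of 0.1, and 17 under cyclic loess. The cause was not tested, apart from the number of genes tested under the filters. Between 10 and 13 lists lay beyond the random lists, against 12. By the mean of members 10 did: key genes, gluconeogenesis, fatty acid synthesis, erythroid and ribosomal protein genes were lost and lipid droplet, lipoprotein and p53 genes gained. Against unmatched random lists only the ribosomal proteins were lost. The share of genes higher in KO ranged with the scaling from 54.0 to 71.6% at 2 months and from 52.7 to 68.6% in the genotype model. Of the named genes' values, 837 kept their side of the threshold, 25 passed it only under an alternative and 6 lost it, and of the list medians 239, 6 and 2 under the filters, scalings and probe set choice. Some values near 0, Sirt6 among them, changed sign, but none past its threshold did. No paired analysis was possible because the labels give no replicate numbers to pair mice or pools by, so arrays were matched by age alone.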

Other observations

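Some of the genes furthest apart between the labels sit beside each other or close to gene families. Nnmt and Zbtb16 are neighbours among the measured genes of chromosome 9, with mean differences of 2.16 and -1.99, and Btbd19 and Plk3 are neighbours on chromosome 4, with 3.44 and 1.55. Apoa4, with -0.99, lies in a run of 3 pattern genes on chromosome 9, and the longest run held 4 genes of the X chromosome. Of the metallothioneins, Mt2 was at -3.09 and -3.71 while Mt1, which was looked up after the data were seen, was at -0.07 and -0.12. Cwc22 has 8 probe sets, 7 of which carry identical values at 3.08 and 1.00, and the remaining one read 0.70 and 0.82, so its difference rests mainly on repeated copies of 1 probe design.

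Y-linked Uty and Eif2s3y read 6.18 and 7.04 in the WT-labelled array at 2 months and 6.37 to 6.63 and 7.27 to 7.43 in the other arrays, while Y-linked Kdm5d read 5.57 against 5.53 to 5.64. Xist, which is expressed from the inactive X chromosome and was below the expression filter, read 4.42 in the WT-labelled array at 2 months and 2.29 to 3.08 in the others. The labels give no sex for the pooled mice, and these genes were looked up after the data were seen.

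Glucocorticoid-responsive genes moved in both directions in the KO-labelled arrays, with 7 of the 17 measured genes of the added list that fell and 4 that rose. Fkbp5, Zbtb16 and Mt2 fell by 2.72, 1.99 and 3.40, whereas Dusp1 and Lcn2 rose by 0.74 and 1.10. The latter 2 were picked from the added list of 17 measured genes after the data were seen. Mt1, on the same list, was at -0.07 and -0.12 without passing. Whether a sequence variant under the probes contributes to the Mt2 value was not tested.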
